A study of Drosophila melanogaster with 18 samples.

How the data were processed

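RNA sequencing counts of 18 libraries of Drosophila melanogaster whole brains were analysed: elav > UAS-bmm-RNAi, elav > + (GAL4 control) and + > UAS-bmm-RNAi (UAS control), each in females and males with 3 libraries. Per the labels, flies were kept at 22 °C, 30 brains per library were dissected at 5 to 6 days after eclosion, and libraries were made from poly(A) RNA with the Illumina Stranded mRNA kit. Groups, sexes and replicate numbers were taken from the sample titles. The deposited table holds whole-number counts per gene, not normalised, for 16612 genes named by symbol, of which 1777 had no count in any library. The submitters' processing notes name STAR 2.5.0b, Cufflinks 2.2.1 and the dm3 genome build. The counting tool, the annotation and the strand setting were not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain.

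Symbols were matched to a Release 6 gene table, which was used only for current names, chromosome arm, gene order and gene span, since its build differs from that of the counts and no coordinates were taken from it. Of the symbols 12410 were current, 3996 matched a unique synonym, 119 were ambiguous and 87 had no match. Genes are named here as in the deposited counts. Total counts were 18531824 to 22576970 per library, scaling factors 0.919 to 1.16, and the most abundant gene took 0.845 to 1.02% of a library. A count of 3 served as the floor of detection, which covers counting error only. The 95% intervals come from the fit and include the spread between libraries.

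Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, 1 coefficient per group over all 18 libraries, robust glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the 9859 tested genes at a threshold of 0.05 with no fold threshold. Log2 fold changes are given with SEs from the fit. The flies labelled knockdown were compared with each control in each sex, and a gene was said to differ from both controls where both tests passed with the same sign. Further tests were the interaction of this effect with sex against the mean of both controls, males against females in each genotype, and GAL4 against UAS control in each sex. For chance overlap of comparisons that share libraries, 20 sets of unchanged groups were simulated, in which at most 1 gene was called in a comparison, so overlap was also counted in lists of the smallest p as long as the real ones, a measure chosen after the data were seen. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, for lists of at least 5 tested genes, with a preset correlation of 0.01 and with an estimated one.

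The rule for named genes, the comparisons and the first set of alternatives were fixed before the data were examined. Tests and alternatives added afterwards are named as such. Named genes were bmm and the 10 higher and 10 lower genes per sex with the largest smaller-of-both fold change among those that differed from both controls at a mean log2 CPM of at least 1. Also named were list members that differed from both controls or otherwise the 2 with the smallest p. They were also the called or 5 smallest-p genes of the interaction, the 5 higher and 5 lower genes with the largest mean change over the 3 genotypes by sex and over both sexes between controls, and the members of the sex determination and background lists. The 33 fixed lists included the target, triglyceride lipolysis and lipid droplets, fatty acid oxidation, fatty acid and sterol synthesis, lipid transport, nuclear oxidative phosphorylation genes, TCA cycle, glycolysis, synaptic transmission, ion channels, neuropeptides, insulin and TOR signalling, glia, eye, fat body, haemocytes, muscle, and antimicrobial and immune response. Further lists were heat shock and chaperones, unfolded protein response, oxidative stress and glutathione, cytochrome P450, circadian clock, activity-regulated genes, lysosome and autophagy, cytosolic and mitochondrial ribosomal proteins, proteasome, ecdysone response, sex determination and dosage compensation, transgene and background markers, mitochondrial genome transcripts, and the double-stranded and small RNA pathway. An ovary list and a testis list were added after the data were examined.

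The procedure was tested on simulated counts with known changes (9690 genes tested). Changes of 1.5, 2 and 4-fold were recovered in 50.7%, 73.1% and 92.4% of cases against the GAL4 control in females, 47.8%, 73.1% and 92.4% against both controls in females. The shares were 46.3%, 68.7% and 93.9% against both controls in males, and 31.3%, 64.2% and 78.8% for the interaction, with 4, 1, 0 and 4 unchanged genes called. The share of 4-fold changes required of this test was lowered from 80% to 70% after the interaction had fallen short of it. No replicate pair agreed within counting noise, so all libraries were kept. The fixed alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, fits on the compared libraries alone, leaving out each library, each control alone and, for the correlation of the sexes, genes with a mean log2 CPM of at least 3. Alternatives added after the data were examined were ovary and testis levels as covariates, leaving out the 3 female replicate 1 libraries, and an offset for a smooth trend on gene length. No library, gene or column of the deposited counts was otherwise left out.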

Results

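Poly(A) RNA from dissected whole brains of adult Drosophila melanogaster was compared between flies with neuronal RNAi against brummer (elav > UAS-bmm-RNAi) and 2 parental controls. The pan-neuronal driver elav-GAL4 directs expression of the RNAi transgene in neurons, and brummer (bmm) encodes the fly homologue of adipose triglyceride lipase. The GAL4 control carried the driver alone (elav > +) and the UAS control carried the RNAi transgene alone (+ > UAS-bmm-RNAi). Each genotype was sampled in females and in males, which gave 6 groups of 3 libraries. Per the labels each library was a biological replicate of 30 brains taken at 5 to 6 days of adult age. The question put to the data was how neuronal RNAi against bmm changes the brain transcriptome in each sex. Gene counts summed to between 18531824 and 22576970 per library, so that 3 counts corresponded to 0.133 to 0.162 CPM, the usual unit of counts scaled by library size. Replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom of 6.64 to 199. Values below are mean CPM ± SD over 3 libraries, or log2 fold changes ± SE from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p over 9859 tested genes. CPM of single genes were also scaled by the TMM factors. Summed CPM of gene lists and the CPM of 3 counts used library size alone.

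Transcripts of other tissues varied between libraries, and so did the level of long genes. The summed CPM of 18 tested ovary genes was 234 in GAL4 female 1, 104 in labelled knockdown female 1, and 37.5 in UAS female 1. It was 28.6 and 22.6 in labelled knockdown females 2 and 3 and 2.75 to 10.5 in the other libraries. The 23 tested testis genes summed to 166 CPM in GAL4 male 2 and to 14.3 to 92.4 CPM in the UAS males and the males labelled knockdown, against 9.92 to 13.5 CPM elsewhere. Eye genes summed to 2208 and 2757 CPM in labelled knockdown females 1 and 2, to 2249 CPM in GAL4 female 1 and to 3072 CPM in UAS female 1. The other libraries had 4358 to 6298 CPM. In the female replicate 1 libraries the 677 genes spanning at least 25.5 kb were lower. Their median log2 deviation was −0.36 in GAL4 female 1, −0.33 in labelled knockdown female 1 and −0.27 in UAS female 1.

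**Figure D1:**
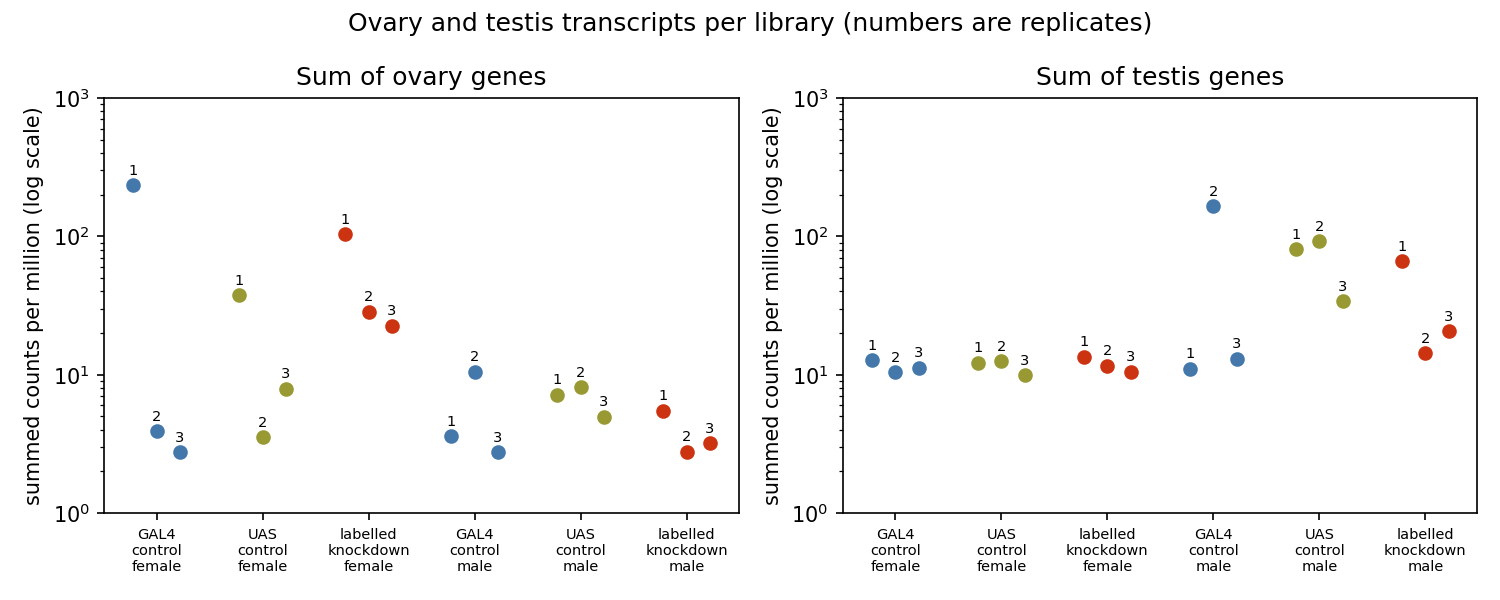
Summed CPM of ovary marker genes and of testis marker genes in each of the 18 libraries, on a logarithmic axis, with the replicate number as the symbol. The female replicate 1 libraries reached 234, 104 and 37.5 CPM of ovary transcripts, and GAL4 male 2 reached 166 CPM of testis transcripts.

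The targeted gene was not lower in the libraries labelled knockdown. In females bmm measured 48.4 ± 3.07 CPM in the libraries labelled knockdown, 45.7 ± 0.721 CPM in the GAL4 control and 45.6 ± 3.77 CPM in the UAS control. In males the corresponding values were 44.6 ± 2.32, 43.2 ± 0.226 and 45.3 ± 0.546 CPM. The log2 fold changes were 0.08 ± 0.06 against the GAL4 control (adjusted p = 0.686) and 0.09 ± 0.06 against the UAS control (adjusted p = 0.853) in females. They were 0.05 ± 0.06 (adjusted p = 0.999) and −0.02 ± 0.06 (adjusted p = 0.989) in males. The lower ends of the 95% intervals lay at 97.1%, 97.2%, 94.4% and 90.2% of the control level in that order. In this fit on all 18 libraries a larger fall of bmm counts in whole brains was thus excluded at this depth. Against the UAS control in males the sign of this small difference turned when labelled knockdown male 1 was left out, to a log2 fold change of 0.0062. The counting tool and its strand setting were not given in the sources used here, so reads of the RNAi hairpin could not be separated from reads of bmm.

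The white gene (w), which encodes a subunit of a pigment precursor transporter and in shortened form marks many transgenes, rose in both sexes of the flies labelled knockdown. Females labelled knockdown measured 255 ± 35.6 CPM against 66.7 ± 25.5 CPM in the GAL4 control and 112 ± 5.85 CPM in the UAS control. Males measured 405 ± 71.8 CPM against 119 ± 23.6 and 115 ± 5.35 CPM. Every one of the 6 libraries labelled knockdown lay above every control library of its sex. Hsp70Bb, a heat shock gene, measured 21.4 ± 9.66 CPM in females labelled knockdown against 3.09 ± 2.60 and 4.17 ± 2.20 CPM in their GAL4 and UAS controls. In males it measured 24.1 ± 1.70 CPM against 3.55 ± 2.44 and 2.72 ± 0.390 CPM. Against the mean of both controls Hsp70Bb rose by 2.59 ± 0.48 in females (adjusted p = 0.0289) and by 2.94 ± 0.48 in males (adjusted p = 0.0215). It was higher than in every same-sex control library in 6 of 6 libraries. Hsp70 genes are near-identical copies, so the copy that gave these counts is uncertain. Over all genes Hsp70Bb passed against the GAL4 control in females (adjusted p = 0.0340). It missed the threshold against the UAS control in females (adjusted p = 0.202) and against both controls in males (adjusted p = 0.0608 and 0.0709).

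**Figure D2:**
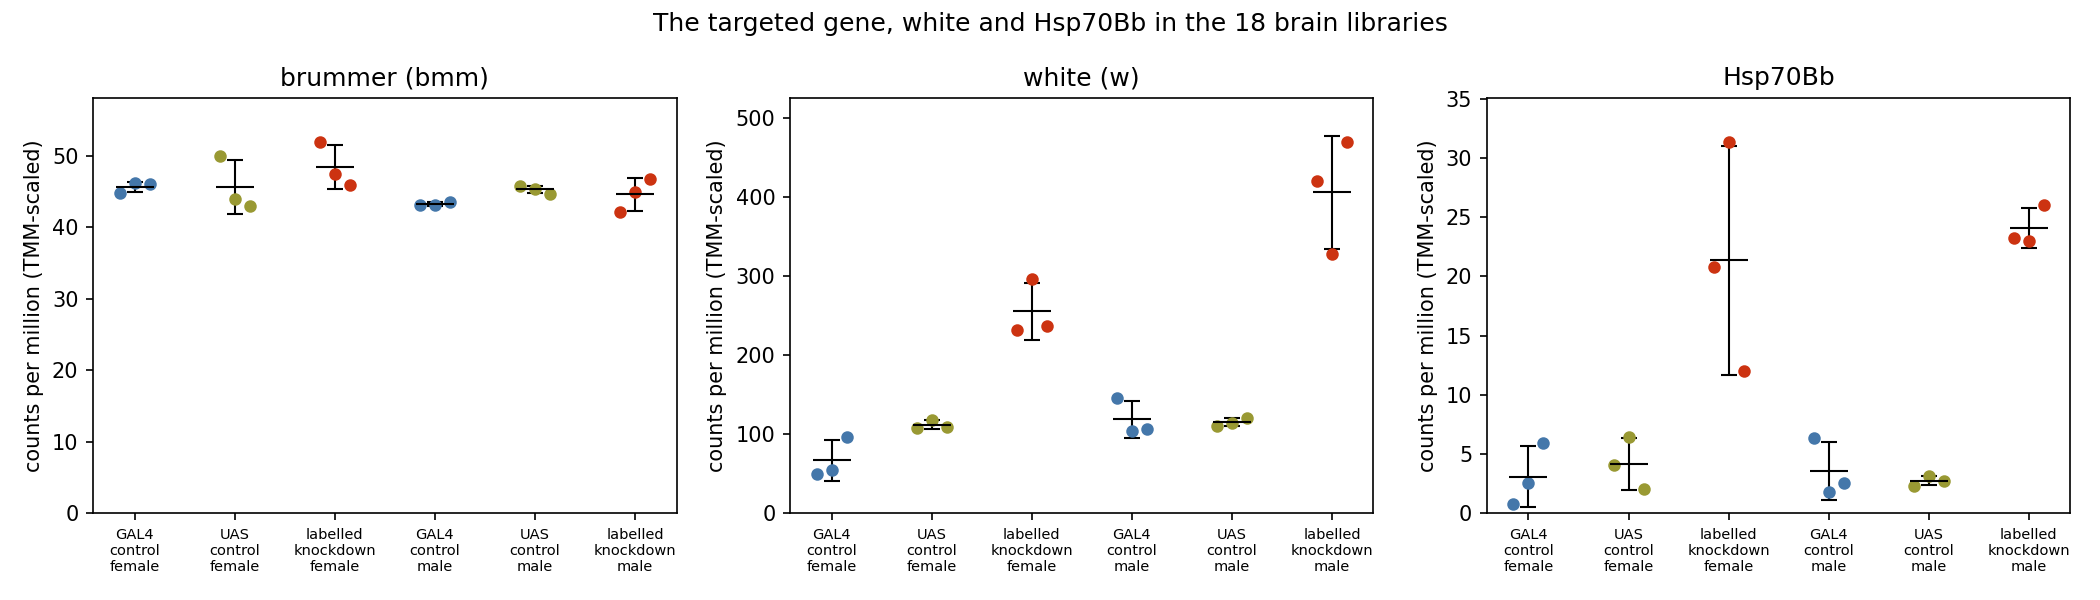
CPM of bmm, w and Hsp70Bb in the 6 groups, with each point a library and the bars the mean ± SD of 3 libraries. The libraries labelled knockdown had bmm at the level of the controls, while all 6 had more w and Hsp70Bb than every control library of their sex.

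In females 13 genes differed from both controls in the same direction, 5 higher and 8 lower in the libraries labelled knockdown. Independent lists would share 0.318, and in 20 simulated sets of unchanged groups 0 genes passed against both controls. Lists as long from these sets, taken by the smallest p with no threshold, shared 9.80 and at most 15 through the common libraries. The simulation drew each gene separately, so it lacks the shared shifts of tissue transcripts and long genes seen between libraries. CR45244, a long non-coding RNA, measured 17.6 ± 2.10 CPM against 9.01 ± 0.447 and 9.22 ± 0.852 CPM in the GAL4 and UAS controls. Tk, which encodes the tachykinin neuropeptides, measured 284 ± 10.8 CPM against 214 ± 2.35 and 217 ± 19.1 CPM. Beside w, the other higher genes were Myo28B1, an unconventional myosin, and CG4078. Against the GAL4 and UAS controls the log2 fold changes were 0.97 ± 0.11 and 0.93 ± 0.11 for CR45244 and 0.40 ± 0.06 and 0.39 ± 0.06 for Tk. They were 0.53 ± 0.11 and 0.81 ± 0.11 for Myo28B1, and 0.41 ± 0.05 and 0.49 ± 0.05 for CG4078. In males the X-linked CG4078 did not pass against both controls. The GAL4 control exceeded the UAS control in CG4078 by 1.26 in males and by 0.08 in females. Among the lower genes mTerf3, a mitochondrial transcription termination factor family member, measured 15.9 ± 1.58 CPM against 48.0 ± 2.87 and 58.0 ± 13.7 CPM. The log2 fold changes were −1.59 ± 0.23 and −1.86 ± 0.23 for mTerf3 and, for GM130, a Golgi matrix protein gene, −0.46 ± 0.09 and −0.60 ± 0.09. The values were −1.90 ± 0.39 and −2.08 ± 0.39 for CG3842, −1.07 ± 0.14 and −0.94 ± 0.14 for CG14715, and −1.19 ± 0.18 and −0.89 ± 0.18 for CG6834. For CHKov1 they were −0.85 ± 0.16 and −0.81 ± 0.16, for CG7054 −0.69 ± 0.17 and −0.91 ± 0.17, and for CG3160 −0.27 ± 0.06 and −0.33 ± 0.06. CHKov1 has the close paralog CHKov2, and reads shared between them could have been split by the counting. The adjusted p values of the 13 genes were at most 0.0478 against each control, and bmm was not among them. CR45244, CG4078, mTerf3 and CG14715 passed against both controls in all 9 fits that each left out 1 of the female libraries. GM130 passed in 8, Tk in 7, Myo28B1 in 6, w in 3, CG3842 in 2, CHKov1 and CG7054 in 1, and CG3160 and CG6834 in 0. The count was 7, 8 and 8 without GAL4 female 1, 2 and 3 and 7 without UAS female 1 or UAS female 2. It was 6, 5 and 8 without labelled knockdown female 1, 2 and 3, and DESeq2 called 29 genes. Without a filter on low counts the count was 8, and without the 3 female replicate 1 libraries it was 4, where CR45244 and CG4078 of the 13 passed and mTerf3 and CG14715 did not. With ovary and testis covariates CG6834, CG7054 and CHKov1 did not pass. With the replicate number as a block the count was 8, and w, CG3842, CG6834, CHKov1 and CG7054 did not pass.

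In males 6 genes differed from both controls in the same direction, 2 higher and 4 lower in the libraries labelled knockdown, in which bmm was not lower. Independent lists would share 0.0976, and in the simulated unchanged groups 0 genes passed against both controls. Lists as long from these groups, taken by the smallest p with no threshold, shared 5.85 and at most 11. CR45244 measured 14.7 ± 1.70 CPM against 8.13 ± 0.246 and 8.88 ± 0.663 CPM in the GAL4 and UAS controls. Its log2 fold changes were 0.86 ± 0.11 and 0.73 ± 0.11 (adjusted p = 0.000501 and 0.00371). The w gene rose by 1.77 ± 0.22 and 1.82 ± 0.22 (adjusted p = 0.000971 and 0.00116). Lower genes were CG10562, at −0.86 ± 0.13 and −0.81 ± 0.13 (adjusted p = 0.00291 and 0.00843), and CG14715, at −1.07 ± 0.14 and −0.79 ± 0.15 (adjusted p = 0.000917 and 0.0296). The weakly expressed CG13502 measured 0.799 ± 0.301 CPM against 2.01 ± 0.153 and 2.14 ± 0.320 CPM. CG11893 was at 0 in 2 of the 3 males labelled knockdown and at 0.101 CPM in the other, against 0.692 ± 0.233 and 0.964 ± 0.0287 CPM in the controls. These last 2 genes lay below the expression limit set for named genes and were chosen after their values were seen. The genes w, CR45244 and CG14715 passed against both controls in both sexes with the same sign. Independent lists would share 0.00426 genes where 3 were shared (Fisher's exact test, two-sided, p = 3.57e-08). In the fits without 1 male library w and CR45244 passed in all 9, CG10562 in 6, CG14715 in 4 and CG11893 and CG13502 in 1. The count was 2 without labelled knockdown male 1, 11 without labelled knockdown male 2, and 3 without labelled knockdown male 3. It was 3, 3 and 2 without UAS male 1, 2 and 3, and DESeq2 called 14 genes. With ovary and testis covariates, and with the replicate number as a block, CG11893 and CG13502 did not pass. Without a filter on low counts CG13502 did not pass.

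**Figure D3:**
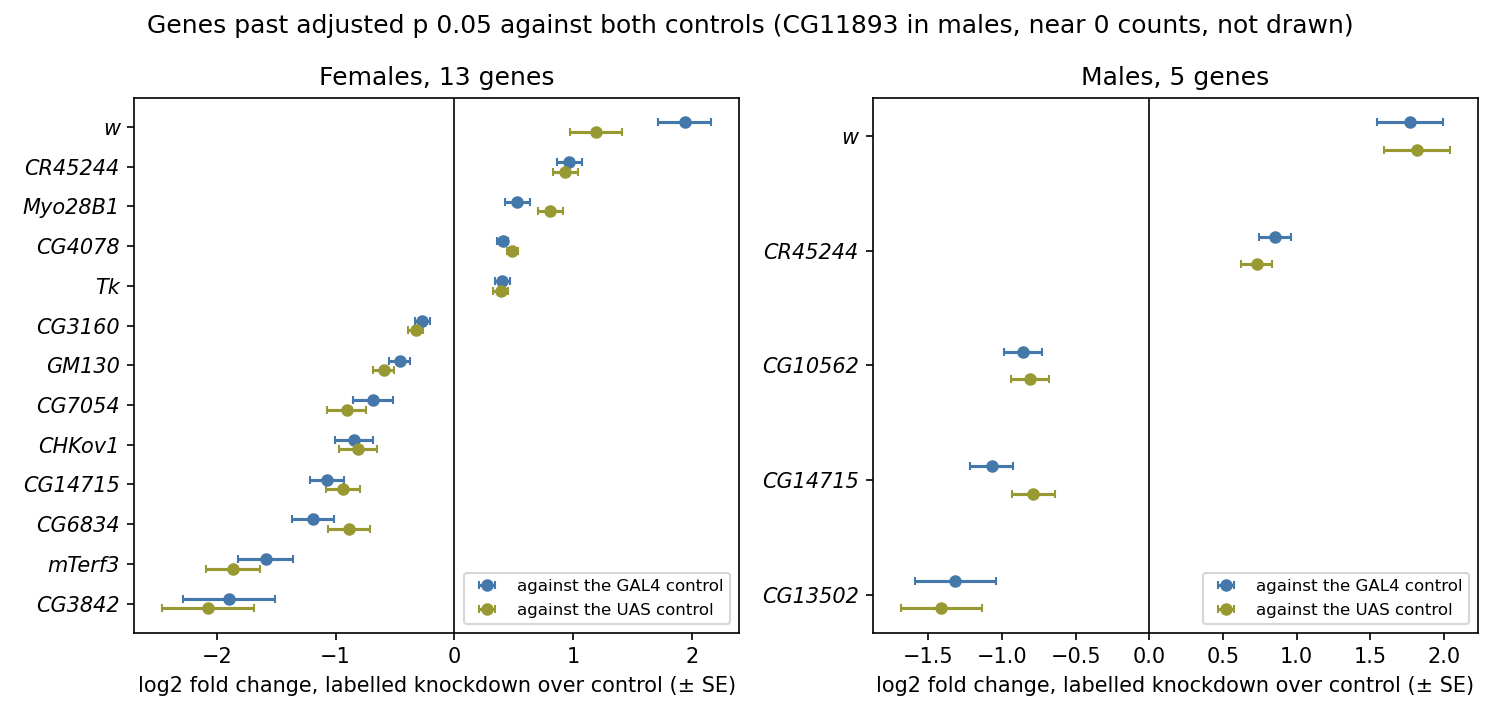
Log2 fold change ± SE of the libraries labelled knockdown against the GAL4 control and against the UAS control for the genes that passed against both, 13 in females and 5 of 6 in males. The sixth male gene, CG11893, is left out because 2 of the 3 males labelled knockdown had no counts of it.

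Against the GAL4 control alone, 193 genes differed in females, 120 higher and 73 lower in the libraries labelled knockdown, where bmm was not lower. wrapper, which encodes a glial immunoglobulin protein, rose by 1.09 ± 0.11 (adjusted p = 5.93e-05), the haemocyte gene Hml by 1.28 ± 0.24 (adjusted p = 0.0125) and DAT, the dopamine transporter, by 0.24 ± 0.06 (adjusted p = 0.0383). Dcr-2, which makes small interfering RNAs, rose by 0.26 ± 0.06 (adjusted p = 0.0260) and the cytochrome P450 gene Cyp6a9 by 2.00 ± 0.21 (adjusted p = 7.11e-05). None of these genes passed against the UAS control, where their log2 fold changes were 0.06 ± 0.11, −0.41 ± 0.23, 0.08 ± 0.06, 0.14 ± 0.06 and −0.17 ± 0.19. Against the UAS control alone, 32 genes differed in females, 17 higher and 15 lower. Higher genes were CG14024 (1.28 ± 0.08, adjusted p = 1.68e-07), the RYamide neuropeptide gene RYa (2.05 ± 0.31, adjusted p = 0.00525) and the RNA interference gene AGO2 (0.51 ± 0.05, adjusted p = 0.000261), and the odorant-binding protein gene Obp99b was lower (−3.74 ± 0.73, adjusted p = 0.0426). None of them passed against the GAL4 control, where their log2 fold changes were −0.13, 0.41, 0.08 and −2.20 in that order. Of the 193 genes, 117 also differed between the UAS and GAL4 controls in the same direction, where 2.44 would be shared by independent lists. Likewise 14 of the 32 also differed between the GAL4 and UAS controls, where 0.396 would be shared. These comparisons share libraries. In 20 simulated sets of unchanged groups, lists as long, taken by the smallest p, shared 35.4 genes on average and at most 45 for the first pair, and 10.7 and at most 15 for the second, which the observed 14 did not exceed. Controls of 3 libraries could not be split, so part of the excess of the 117 may come from the shared libraries. The first count was 91, 113 and 125 without labelled knockdown female 1, 2 and 3 and 128 without GAL4 female 3. The second was 15 and 20 without labelled knockdown female 2 and 3 and 21, 20 and 17 without UAS female 1, 2 and 3. DESeq2 called 175 higher and 134 lower genes against the GAL4 control and 80 genes against the UAS control, and fits on the compared libraries alone called 76 and 5. Without the 3 female replicate 1 libraries 17 differed from the UAS control, and 21 with the replicate number as a block.

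Against the GAL4 control alone, 80 genes differed in males, 53 higher and 27 lower in the libraries labelled knockdown, in which bmm was not lower. wrapper rose by 0.66 ± 0.11 (adjusted p = 0.00573), Cyp6a9 by 2.10 ± 0.21 (adjusted p = 8.28e-05) and aub, a gene of the Piwi-interacting RNA pathway, by 0.68 ± 0.15 (adjusted p = 0.0441). None of them passed against the UAS control, where their log2 fold changes were −0.15, −0.42 and 0.04. Against the UAS control alone, 26 genes differed, 10 higher and 16 lower. CG14024 was at 1.29 ± 0.08 (adjusted p = 3.26e-08), AGO2 at 0.43 ± 0.05 (adjusted p = 0.000860) and Cyp4ac3 at −0.56 ± 0.08 (adjusted p = 0.00130). Against the GAL4 control these were at −0.02, 0.04 and −0.22, and none passed. Of the 80 genes, 65 also differed between the UAS and GAL4 controls in the same direction (0.771 for independent lists). Of the 26 genes 17 also differed between the GAL4 and UAS controls (0.250 for independent lists). Lists as long from the simulated unchanged groups shared 18.4 and at most 25 for the first pair and 8 and at most 13 for the second, and part of the excess may come from the shared libraries. Females and males shared 70 genes against the GAL4 control and 13 against the UAS control. The first count was 28 and 33 without labelled knockdown male 1 and 3 and 41, 43 and 35 without GAL4 male 1, 2 and 3. The second was 15 without labelled knockdown male 1 and 17 without UAS male 1 or UAS male 3. DESeq2 called 137 and 60 genes, and a fit on the compared libraries alone called 38 against the GAL4 control.

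Genes of lipid and energy metabolism did not differ from both controls in either sex. None of the 184 tested members of 7 lists passed against both controls with edgeR, over all genes or adjusted over the list alone. The lists held 19 genes of triglyceride lipolysis and lipid droplets including bmm, 24 of fatty acid oxidation, 23 of fatty acid and sterol synthesis, 16 of lipid transport, 69 nuclear genes of oxidative phosphorylation, 20 of the TCA cycle and 15 of glycolysis. The lipolysis list also took in T-cp1, a chaperonin subunit gene, by a shared symbol, so not every member is a lipid gene. In females 0 of the 184 members and in males 1 (NDUFS3) had an unadjusted p under 0.05 against both controls with the same sign, and DESeq2 called 0 in each sex. Members with the smallest p against the mean of both controls in females were CG4729 (0.08 ± 0.04) and Pect (0.11 ± 0.06) of the lipolysis list, CG9527 (−0.10 ± 0.04) of fatty acid oxidation. Others were AcCoAS (0.11 ± 0.06), an acetyl-CoA synthase, fabp (0.24 ± 0.10), a fatty acid binding protein, Mdh1 (0.12 ± 0.06) and Pglym78 (0.10 ± 0.06). Of the oxidative phosphorylation list these were NDUFS3 (−0.18 ± 0.07) and CG10396, with the smallest p of the 7 lists in females (1.98 ± 0.69, adjusted p = 0.365). CG10396 measured 1.25 ± 0.331 CPM against 0.0848 ± 0.113 CPM in the GAL4 and 1.15 ± 0.171 CPM in the UAS control, with adjusted p = 0.0508 against the former and 0.978 against the latter. In males they were CG3812 (0.10 ± 0.05), T-cp1 (−0.09 ± 0.06), Mfe2 (0.12 ± 0.04), GLaz (−0.26 ± 0.08), an apolipoprotein D homologue, NDUFS3 (−0.22 ± 0.07), SdhA (−0.06 ± 0.05) and Eno (0.07 ± 0.06). Of the synthesis list they were v(2)k05816 (−1.66 ± 0.89) and Cyp4g1 (−3.04 ± 1.63), with large errors. The adjusted p of these members was at least 0.365 in females and 0.579 in males. In simulated data with known changes, 73.1% of 2-fold and 47.8% of 1.5-fold changes were recovered against both female controls, and 68.7% and 46.3% against both male controls. These data held 67 changed genes at each of these folds and drew each gene separately. The real comparisons with the UAS control called 32 genes in females and 26 in males. With so few calls the adjustment is stricter, so the share recovered in the real data may be lower.

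Of the neuronal gene lists, 1 of 35 tested neuropeptide genes (Tk) rose against both controls in females. In males 0 of 35 passed with edgeR, 1 (Tk) had an unadjusted p under 0.05 against both controls and DESeq2 called 0. Adjusted over the list alone, 2 rose in females and 0 in males. AstA, the allatostatin A gene, was the one added, with log2 fold changes of 0.22 ± 0.06 and 0.26 ± 0.06 against the GAL4 and UAS controls. In males Tk measured 0.22 ± 0.06 and 0.18 ± 0.06. None of 29 synaptic transmission genes or 29 ion channel genes passed against both controls in either sex, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. The ion channel genes, which span a median of 36.3 kb, had a median log2 fold change of −0.31 in females, in whom long genes were lower in several libraries. Of 14 clock genes per, the period gene, was lower in females when adjusted over the list alone (−0.44 ± 0.13 and −0.47 ± 0.13) but not over all genes (adjusted p = 0.142 and 0.281). DESeq2 called 0 clock genes in each sex, and in males edgeR called 0, with 0 at an unadjusted p under 0.05.

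Among the remaining lists, w was the member called against both controls over all genes, as 1 of 6 tested transgene and background markers. Adjusted over the list alone, Hsp70Bb of 15 heat shock and chaperone genes rose in both sexes, and Obp99b of 18 fat body genes was lower in males (−1.62 ± 0.44 and −1.79 ± 0.44). DESeq2 called these genes over all genes too. In the following lists no member passed with edgeR in either sex, over all genes or adjusted over the list alone, and DESeq2 called 0. They held 20 insulin and TOR signalling, 24 glial, 29 eye, 13 haemocyte, 20 muscle, 28 antimicrobial and immune, 20 unfolded protein response, 27 oxidative stress and glutathione, 56 cytochrome P450 and 15 activity-regulated genes. The others held 28 lysosome and autophagy, 85 cytosolic ribosomal protein, 72 mitochondrial ribosomal protein, 31 proteasome, 16 ecdysone response, 17 sex determination and 15 double-stranded and small RNA pathway genes. Members of these lists with an unadjusted p under 0.05 against both controls with the same sign were, in females, 2 glial genes (CG9657 and Gs2), 4 muscle genes (Act57B, Mhc, Prm and up), sip3 of the unfolded protein response, Atg6 and park, the fly parkin gene, of lysosome and autophagy, and Dcr-2. In males they were GstE7, Cyp312a1, Cyp4ac3 and park. The park log2 fold changes were −0.29 ± 0.07 in females and −0.26 ± 0.07 in males against the mean of both controls (adjusted p = 0.0905 and 0.322). The names CG9657, Gs2, Act57B, up, Atg6, sip3, GstE7 and Cyp312a1 are given because of these p values, some of them after the values were seen. Of the 18 ovary and 23 testis genes 0 passed with edgeR, 0 had an unadjusted p under 0.05 against both controls, and DESeq2 called 2 ovary genes in males. No gene of the list for transcripts of the mitochondrial genome was present.

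As groups, muscle genes were lower than the remaining genes in the libraries labelled knockdown in both sexes against the mean of both controls. The median log2 fold change was −1.70 in females (camera with a preset correlation, adjusted p = 1.76e-08) and −1.25 in males (adjusted p = 0.000124). The calls were lost with adjusted p = 0.642 in females and 0.813 in males with an estimated correlation. Mhc, the muscle myosin heavy chain, measured 1.89 ± 0.244 CPM in females labelled knockdown against 34.4 ± 30.0 and 20.1 ± 15.5 CPM, while the summed muscle list was 855 ± 13.4 CPM against 953 ± 252 and 851 ± 68.2 CPM. The sums were not TMM-scaled, unlike the Mhc values. In females glial genes were higher (median 0.08, adjusted p = 0.0441) and eye genes lower (median −0.60, adjusted p = 0.0232), in libraries of which 2 of 3 had low eye transcripts. These calls were lost with adjusted p = 0.642 and 0.958 with an estimated correlation. In males cytosolic ribosomal protein genes (median −0.08, adjusted p = 4.46e-10), nuclear oxidative phosphorylation genes (median −0.05, adjusted p = 0.000945) and oxidative stress genes (median −0.07, adjusted p = 0.0457) were lower. Fat body genes were lower too (median −0.34, adjusted p = 0.00656), with a summed CPM of 1737 ± 61.5 against 1850.1 ± 153 and 1961 ± 113. The calls of these 4 male lists were lost with adjusted p = 0.813 with an estimated correlation. Of 31 lists 3 thus passed with a preset correlation in females and 5 in males, against 7 and 2 with the GAL4 control alone and 14 and 8 with the UAS control alone. Log2 fold changes also followed gene length, with Spearman coefficients of −0.29 in females and 0.40 in males across 6769 genes, which are not independent replicates. With an offset for length, chosen after the data were seen, 2 female and 3 male lists passed. With the replicate number as a block more male lists passed than without it.

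The difference between the sexes in the effect seen in the libraries labelled knockdown, in which bmm was not lower, was tested as an interaction, and 1 gene passed. Cbs, which encodes cystathionine beta-synthase, differed by −1.95 ± 0.08 in males and −0.27 ± 0.07 in females against the mean of both controls. The interaction was −1.68 ± 0.10 (adjusted p = 2.96e-07). Cbs measured 5.37 ± 0.130 CPM in males labelled knockdown, 7.07 ± 0.426 CPM in GAL4 males and 60.9 ± 2.42 CPM in UAS males. The corresponding females had 43.3 ± 2.88, 39.3 ± 4.70 and 69.0 ± 2.11 CPM. The next smallest p values belonged to CG14798 (−1.07 ± 0.20, adjusted p = 0.301), CG14711 (−0.32 ± 0.08), ssx (−0.39 ± 0.10), a relative of Sex-lethal, and CG4078 (0.22 ± 0.06). The last 3 had an adjusted p = 0.972, and none of these 4 passed. bmm did not differ by sex in this test (−0.07 ± 0.07, adjusted p = 0.972). Across genes, which are not independent replicates, the log2 fold changes of females and males had a Pearson coefficient of 0.24 and a Spearman coefficient of 0.07, and 50.8% had the same sign. Over the 6847 genes with a mean log2 CPM of at least 3 these were 0.12 and −0.03. With the GAL4 control alone the Spearman coefficient was 0.26 with 61.3% of the same sign, and with the UAS control alone 0.00134 with 45.7%. With the UAS control alone 4 genes passed the interaction and with the GAL4 control alone 0 (edgeR), and against the mean of both controls DESeq2 called 4 and a fit with ovary and testis covariates 2. Among lists, 9 of 31 passed camera with a preset correlation and 0 with an estimated one (adjusted p = 0.823 with an estimated correlation for each of the 9). In the male minus female effect eye (median log2 1.16), ion channel (0.34), heat shock (0.41), ecdysone response (0.29) and synaptic genes (0.08) were higher. Cytosolic ribosomal (−0.11), mitochondrial ribosomal (−0.07), oxidative phosphorylation (−0.05) and neuropeptide genes (median −0.09 but mean 0.17) were lower. This effect followed gene length with a Spearman coefficient of 0.46. With the length offset (camera, preset correlation) eye, heat shock, ecdysone response and cytosolic ribosomal genes still passed. Ion channel (adjusted p = 0.0892), synaptic (0.274) and neuropeptide genes (0.124) did not. Mitochondrial ribosomal (adjusted p = 0.707) and oxidative phosphorylation genes (0.742) did not pass either and turned to the higher side. Lipid transport and fat body genes passed as lower (adjusted p = 0.0484 each). Summed eye genes ranged from 2208 to 4745 CPM in the females labelled knockdown and from 5494 to 6298 CPM in the males. Summed ion channel genes ranged from 7586 to 13969 CPM in these females and from 13086 to 16556 CPM in these males.

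**Figure D4:**
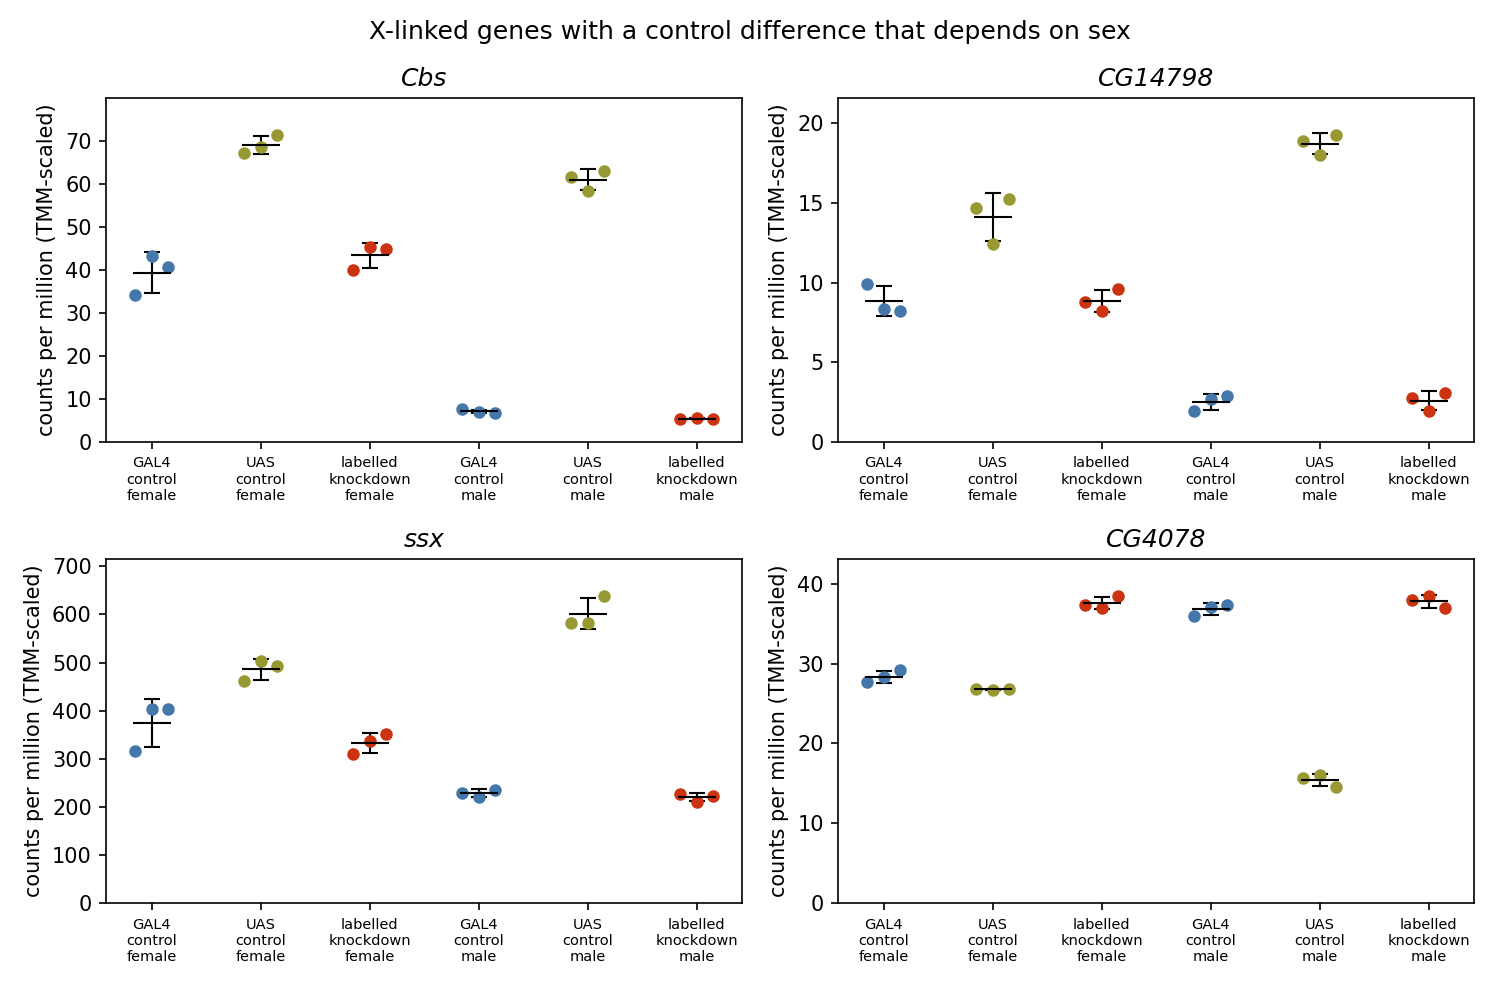
CPM of Cbs, CG14798, ssx and CG4078 in the 6 groups, with each point a library and the bars the mean ± SD of 3 libraries. In males the libraries labelled knockdown sit with the GAL4 control, at 5.37 and 7.07 CPM of Cbs against 60.9 CPM in the UAS control.

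Males and females differed in 356 genes in the flies labelled knockdown (160 higher in males) and in 293 in the UAS control (141 higher in males). In the GAL4 control 166 genes were higher and 146 lower in males. In all 3 genotypes 144 genes differed with the same sign, 70 higher in males and 74 higher in females. The dosage compensation RNA roX1 measured 3551 ± 73.9 CPM in GAL4 males and 8.46 ± 2.27 CPM in GAL4 females. Its log2 fold change was 8.71 ± 0.16 in the GAL4 control, 8.18 ± 0.16 in the UAS control and 8.41 ± 0.16 in the flies labelled knockdown. In the same order roX2 differed by 8.35 ± 0.12, 7.69 ± 0.12 and 8.34 ± 0.12. brv3 and CG4586 were also higher in males, by 5.87 ± 0.52 and 4.93 ± 0.34 in the GAL4 control. CG3706 measured 2.25 ± 0.887 CPM in GAL4 males against 0.0519 ± 0.0513 CPM in females. The yolk protein genes Yp1, Yp2 and Yp3 were lower in GAL4 males, at −5.77 ± 1.13, −5.48 ± 0.83 and −6.05 ± 0.83, and so was the chitinase gene Cht2, at −5.00 ± 0.38. CR45629 measured 6.33 ± 1.75 CPM in GAL4 females and 0 in the 3 GAL4 males and the 3 males labelled knockdown. Of 17 tested sex determination and dosage compensation genes, dsx, msl-2, roX1 and roX2 were higher and fit, Yp1, Yp2 and Yp3 lower in males of all 3 genotypes. tra passed, lower in males, in the GAL4 control, and whether its sex difference varied between genotypes was not tested. In the flies labelled knockdown the count was 218 and 211 without female 1 or 2 and 229, 202 and 203 without male 1, 2 or 3. In the controls it was 206 and 193 without GAL4 male 1 or 3, and 175 and 191 without UAS female 2 or 3 and 171, 190 and 193 without UAS male 1, 2 or 3. DESeq2 called 563, 523 and 473 genes in the flies labelled knockdown, the GAL4 and the UAS control. With ovary and testis covariates the count was 200 in the flies labelled knockdown and 186 in the UAS control, and a fit on the compared libraries alone called 85 in the GAL4 control.

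The 2 controls, which differ in which transgene they carry, differed from each other in 245 genes in females (114 higher in the GAL4 control) and 188 in males (91 higher), with 123 genes in both sexes with the same sign. Of these 56 were higher in the GAL4 control and 67 in the UAS control, where independent lists would share 2.34. Higher in the GAL4 control were spdo, a regulator of Notch signalling, by 2.18 ± 0.30 in females and 2.42 ± 0.30 in males, and RnrL, a ribonucleotide reductase subunit, by 2.14 ± 0.22 and 1.97 ± 0.22. So were CR32207 by 2.22 ± 0.34 and 2.11 ± 0.35, CG11391 by 1.84 ± 0.42 and 1.72 ± 0.39, and CG13794 by 1.88 ± 0.31 and 1.59 ± 0.31. Adh, alcohol dehydrogenase, was higher by 0.96 ± 0.13 and 0.96 ± 0.14, the 1 of 6 background markers that differed in both sexes. Higher in the UAS control were CR45435 (−4.58 ± 0.54 and −5.08 ± 0.54), CR44291 (−4.01 ± 0.32 and −4.71 ± 0.34) and CG14563 (−4.24 ± 0.53 and −4.29 ± 0.55), with CG31664 (−2.62 ± 0.33 and −2.89 ± 0.33) and Cyp6a9 (−2.17 ± 0.21 and −2.53 ± 0.21). The female count was 161 without GAL4 female 1 and 137 without UAS female 2, and the male count was 118, 116 and 117 without GAL4 male 1, GAL4 male 3 and UAS male 2. In females DESeq2 called 402 genes and a fit with ovary and testis covariates 405. A fit on the compared libraries alone called 66 and the fit without the 3 female replicate 1 libraries 145.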

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

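The tests of bmm by w, by Hsp70Bb and by the lower bound, of the smallest p over splits, of splits within replicate numbers, of neighbouring genes among those that differed from both controls, of the X chromosome, and the choice of the explanations they address were made only after the results were seen, and so were the ovary, testis and gene length corrections.

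In 6 tests the effect differed between the sexes by a test of the difference itself. In males minus females the difference of Cbs in the libraries labelled knockdown from the mean of both controls was −1.68 on the log2 scale. No gene passed this test with the GAL4 control alone, so this value is not separate from the difference between the controls. The difference between the GAL4 and UAS controls was −2.29 for Cbs, −2.23 for CG14798, 1.18 for CG4078 and −1.02 for ssx, which are all X-linked, and 0.55 for Ac78C, an adenylyl cyclase gene on chromosome arm 3L.

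The first pattern was that bmm was not lower in the libraries labelled knockdown. Libraries that in truth held a control genotype would not have more w than the controls, yet w lay above every same-sex control library in 6 of 6. Whether the driver and the transgene act together stays open: Hsp70Bb, part of which some vectors carry, exceeded the sum of both same-sex control means in 6 of 6 while 0 of 14 other heat shock genes lay above every control in 5 or more, but w exceeded that sum in 6 of 6 too, which needs no driver. Reads of bmm from cells that the driver does not reach, or from the hairpin itself, may hide a fall in neurons and stay open, since the lowest of the 4 lower 95% bounds was 90.2% of the control and neurons were not measured alone. An ineffective hairpin and a fall of the protein without a fall of the RNA were not tested.

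The second pattern was the set of 16 genes that differed from both controls in either sex. Ovary and testis RNA and the gene length trend were excluded as its whole cause, since 19 of 19 calls kept at least 50% of both fold changes with ovary and testis covariates and 19 of 19 with a length offset. With the covariates 5 of these calls nonetheless ended (CG6834, CG7054 and CHKov1 in females, CG11893 and CG13502 in males). Their errors grew at folds of nearly the same size, save CHKov1, whose fold against the UAS control went from −0.81 ± 0.16 to −0.73 ± 0.17. The size of the CG11893 fold is not determined, as labelled knockdown males 1 and 3 had no counts of it. Linked variants of the parental stocks may contribute, since 8 pairs of these genes lay within 50 tested genes of each other on 1 chromosome arm, against a median of 1 in 10000 random sets (permutation test, p = 3e-04, or p = 2e-04 without w), with CG14715, CG6834 and Tk close together on 3R and CG11893, CG10562 and CHKov1 at another place on 3R. A hypothesis is that alleles carried by both stocks, but not by the chromosomes they were outcrossed to, are homozygous only in the flies labelled knockdown, which allele counts from the reads would test and gene counts cannot, and an effect of the RNAi itself on some of these genes remains open and untested.

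The third pattern was that the 2 controls differed in 123 genes in both sexes. Ovary and testis RNA was excluded as its whole cause, as 123 of 123 genes kept at least 50% of both fold changes with the covariates and 110 of them were still called in both sexes. Linked variants may account for much of it, since 35 pairs lay within 5 tested genes of each other (median of random sets 7, permutation test, p = 1e-04, the smallest that 10000 random sets can give). Sons that carry only the X chromosome of the GAL4 stock in both genotypes with the driver would resemble the GAL4 control at X-linked genes, and 68% of 25 X-linked genes that differed between control males lay nearer the GAL4 control in the males labelled knockdown, against 23.0% of 161 autosomal genes (Fisher's exact test, two-sided, p = 1.53e-05). Females gave 56.5% of 23 and 23.9% of 218 (Fisher's exact test, p = 0.00206). X-linked genes were not in excess among the placed genes that differed between the controls. They made up 13.4% of these in males against 16.8% of tested genes (Fisher's exact test, p = 0.236). In females they were fewer, at 9.54% against 16.8% (Fisher's exact test, p = 0.0016). All these tests take genes as independent, while genes of the same libraries are not independent replicates and linked genes may move together. The parent that gave the driver is not stated, so this reading of Cbs and its X-linked neighbours stays a hypothesis.

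Other splits of the same libraries were fitted to ask whether chance can be excluded, each with the libraries of the groups compared alone, so that the real counts differ from those of the fit on all libraries. For the number of genes that differed from both controls in females it is not clear. That fit called 9, of which 6 were among the 13 of the report, and 2 of 100 splits gave at least as many (highest other 61), while 3 held a gene with as small a p. Of 100 splits that exchanged only libraries of the same replicate number, 5 gave at least as many (highest other 77) and 9 held as small a p. Splits can keep a whole genotype together, as the highest other of 61 did with the 3 GAL4 libraries. Such splits measure a difference of genotype, so these shares do not decide whether chance can be excluded. For the number in males it is not clear either. At least the real 6, 4 of them among the 6 of the report, were given by 5 of 100 splits (highest other 41). A gene with as small a p was held by 10 of 100. The highest other again had the 3 GAL4 libraries in the place of the libraries labelled knockdown. The smallest other p belonged to Cbs, which differs between the controls. The genes w, CR45244 and CG14715 of the report's 6 also passed with the same sign in the female libraries. Independent lists would share 0.00426 there (Fisher's exact test, two-sided, p = 3.57e-08), a test that takes genes as independent. In the 9 fits without 1 library CR45244 passed in all in each sex. In these fits w passed in 3 in females and CG14715 in 4 in males. Without the 3 female replicate 1 libraries w and CG14715 did not pass in females. That fit has fewer libraries, so these lost calls do not decide whether the overlap excludes chance for w and CG14715. The level of w nonetheless lay above every same-sex control library in 6 of 6 libraries labelled knockdown. For the number of genes in the interaction chance cannot be excluded, as 15 of 100 splits gave at least the real 1, with up to 1310. For Cbs itself it can, as 1 of 100 splits, the real one, held a gene with a p as small as that of Cbs, and 3 of 100 when only libraries of the same number were exchanged. That interaction rests on the UAS control, as no gene passed with the GAL4 control alone. The comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real and highest other counts were 76 and 602 against the GAL4 control in females (2 splits as large), 5 and 1232 against the UAS control in females (2), and 38 and 70 against the GAL4 control in males (2). They were 29 and 2 against the UAS control in males (1). For sex they were 270 and 1 in the flies labelled knockdown, 85 and 0 in the GAL4 and 265 and 0 in the UAS control (1 each). They were 66 and 5 and 253 and 0 between the controls in females and males (1 each). Splits that called several times the real count point to a structure of the samples. Against each control in females the highest put the replicate 1 libraries and labelled knockdown female 2 together, and in the interaction the highest put the 3 female replicate 1 libraries in 1 group. The highest against both controls put the 3 GAL4 libraries in the place of the libraries labelled knockdown, in females as in males. It thus set the GAL4 genotype against mixtures of labelled knockdown and UAS libraries, so its count can come from the genotype.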

How the results depend on the processing

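The ovary and testis covariates, the fits without the 3 female replicate 1 libraries and the gene length offset were chosen after seeing the data, and all other alternatives were fixed before. RLE scaling left every count of genes within 1.5 times its value, and of 117 called values of named genes it kept 117, DESeq2 117, no filter 106 and the replicate block 105, with none reversed. The cause of the following changes was not tested. DESeq2 called 3.1e+02 genes (175 higher and 134 lower) against the GAL4 and 80 against the UAS control in females, 137 and 60 in males, and 29 and 14 against both. It called 4 for the interaction, 563, 523 and 473 by sex in the flies labelled knockdown, the GAL4 and the UAS control, and 402 between the controls in females. Without a filter 8 female genes differed from both controls. Fits on the compared libraries alone called 29 against the UAS control and 253 between the controls in males, more than the fit on all libraries, and fewer by over 1.5 times in 5 comparisons: 76 against the GAL4 and 5 against the UAS control in females, 38 against the GAL4 control in males, 85 by sex in the GAL4 control and 66 between the controls in females. With the covariates, calls against both controls ended for CG6834 (−0.89 ± 0.18 to −0.90 ± 0.19 against the UAS control, adjusted p = 0.107), CG7054 (−0.69 ± 0.17 to −0.70 ± 0.19 against the GAL4 control, adjusted p = 0.0618, and −0.91 ± 0.17 to −0.93 ± 0.19 against the UAS control, adjusted p = 0.0588) and CHKov1 (adjusted p = 0.119 against the UAS control) in females. In males they ended for CG11893 (−4.54 ± 0.85 to −4.45 ± 0.89, adjusted p = 0.05003) and CG13502 (−1.41 ± 0.28 to −1.45 ± 0.32, adjusted p = 0.109) against the UAS control. CG11893 had no counts in labelled knockdown males 1 and 3, so the size of its fold is not determined. In the same fit the interaction gave 2 genes, sex 200 in the flies labelled knockdown and 186 in the UAS control, and the female controls 405. Without the 3 female replicate 1 libraries 17 genes differed from the UAS control, 4 from both controls (2 of the 13, CR45244 and CG4078) and 145 between the controls, and bmm differed from the mean of both controls by 0.06 ± 0.05 (95% interval −0.05 to 0.17, adjusted p = 0.693). The interaction gave 0 genes with the GAL4 control alone and 4 with the UAS control alone. Of 31 gene lists, 0 passed in females, males and the interaction with an estimated correlation. With the GAL4 control alone 7 in females and 2 in males passed, with the UAS control alone 14 and 8, and 3 in males with the length offset. The correlation of the sexes was 0.12 (Pearson) and −0.030 (Spearman, reversed) at a mean log2 CPM of at least 3, and Spearman's coefficient was 0.26 with the GAL4 control alone and 0.00134 with the UAS control alone. Leaving out each library in turn gave 91 to 172, 15 to 23, 28 to 119 and 15 to 30 genes against the GAL4 and UAS controls in females and then males, 5 to 9 and 2 to 11 against both, and 1 to 1 for the interaction. It gave 202 to 296, 193 to 341 and 171 to 243 by sex, and 137 to 283 and 116 to 178 between the controls. bmm ranged from 0.04 to 0.13 and 0.03 to 0.14 in females and from 0.01 to 0.09 and −0.067 to 0.0062 in males, the last turning sign without labelled knockdown male 1. In simulated data at this depth, of 1.5-fold changes 47.8% were recovered against both female controls, a share that may be lower in the real data.

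The replicate number as a block gave 21 genes against the UAS control in females, 8 against both controls in females and 9 male gene lists. Of the female genes that differed from both controls, w, CG3842, CG6834, CHKov1 and CG7054 were not called under the block, nor were CG11893 and CG13502 of the male genes (4 called). The numbers do not pair the libraries as a whole: 13 of 45 same-number pairs had a correlation of their deviations over 0.1, with the lowest at −0.60, and 0 libraries were best matched by their own number in every other group. In females 7 of 9 pairs were over 0.1, with the lowest at −0.097, and the 3 number 1 pairs had 0.45 to 0.55. For the GAL4 and UAS control females all 3 pairs were over 0.1 (0.55, 0.31 and 0.10). GAL4 female 2 with UAS female 3 and GAL4 female 3 with UAS female 2 were higher, however, at 0.41 and 0.24. Only the number 1 libraries were thus best matched by number. For these controls the block gave 258 genes where 245 were called without it. In this comparison 4 of the 10 splits part all 3 same-number pairs, of which the real one called 66 and the others at most 0.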

Other observations

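The naming of genes in the following values beyond the fixed rule was made after the data were seen, and nothing here was tested further. Of 35 tested neuropeptide genes 10 were lower in males in the flies labelled knockdown, 7 in the GAL4 control and 3 in the UAS control, where Dh31 was higher. Hug, Ilp3 and Proc were lower in all 3, and in the GAL4 control their log2 fold changes were −0.79 ± 0.13, −1.82 ± 0.14 and −1.02 ± 0.08. Among 13 haemocyte genes 3, 1 and 5 were lower in males of the same genotypes, with NimC4 at −1.85 ± 0.38 in the GAL4 control. Obp99b was higher in males of all 3 genotypes, by 4.46 ± 0.53 in the GAL4 control. Among the lipid lists, Seipin, a lipid droplet assembly gene, was higher in males in all 3 genotypes (0.84 ± 0.18 in the GAL4 control) and so was CG17544 of the fatty acid oxidation list (0.35 ± 0.06).

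Between the controls, wrapper was lower in the GAL4 control, at −1.03 ± 0.11 in females and −0.82 ± 0.11 in males. AGO2 was higher by 0.43 ± 0.05 and 0.39 ± 0.05, and CG14024, on the list of activity-regulated genes, by 1.41 ± 0.08 and 1.30 ± 0.08. Of 56 cytochrome P450 genes 7 differed between the controls in each sex, 5 of them lower in the GAL4 control in females and 6 in males. Without labelled knockdown male 2, 11 genes differed from both controls in males, 9 lower and 2 higher. That library lay between the other males labelled knockdown and the controls for mTerf3 (29.4 CPM against 14.7 and 16.1) and CG6834 (32.9 CPM against 15.7 and 20.5).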
